A study of Mus musculus with 24 samples.

How the data were processed

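Gene expression was measured in single cells of the cortex of 24 mice on a C57BL/6 background with an amyloid model, 1 library per mouse, on a droplet 3' platform. Per the labels' protocols the mice were perfused with saline, the tissue was dissociated with enzymes, and myelin, red blood cells and dead cells were removed before loading. The mice were grouped by the labels into E3_C, E3_T, E4_C and E4_T, with 6 mice per group and 3 per sex; mice are named by group, number and sex, as in E3_T 1-M. The labels name no batch. Sample titles run from 1 to 24 and fall into runs of 8. Titles 1-8 hold 4 E3_C and 4 E3_T mice, and titles 9-16 hold 6 E4_C and 2 E3_C mice. Titles 17-24 hold 6 E4_T and 2 E3_T mice. Within each run each sex fills a block of 4 consecutive titles.

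The deposited values are raw counts of UMIs per gene and barcode, 1 matrix per library with 31,053 genes. The barcodes had been called and the reads counted with Cell Ranger against genome build mm10, and Seurat 4.0 was used downstream, per the submitters' processing notes and the file headers; the Seurat objects were not used here. Gene positions come from the GENCODE vM21 annotation of mm10 and were found for 30,934 of the 31,053 genes and for 9342 of the 9347 genes tested in microglia. No APOE, Cre or amyloid transgene feature was analysed here, and Clec7a, which the naming rule lists, was not analysed here. Some genes that meet the naming rule are not reported here.

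Everything that follows was computed from these counts with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0). Groups, tests, covariates, gene lists, marker lists, thresholds and a set of alternatives were fixed before the data were examined. Cells of the main filter have at least 500 genes and under 10% mitochondrial UMIs. Doublets were scored per library with the Scrublet method in scanpy. Its own threshold marked almost no cells, so the highest scores were removed at a rate of 0.8% per 1000 barcodes, a change made after the data were seen. The looser filter, at least 200 genes and under 25% mitochondrial UMIs, was also added after the data were seen, because the main filter kept few cells.

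Cells of all libraries under the looser filter were clustered together without integration. Counts were scaled to cell totals and logged, 2000 variable genes (without mitochondrial, ribosomal and sex-linked genes) were reduced to 30 principal components, and the graph of 15 neighbours was cut by the Leiden method at resolution 1 (seed 0). Clusters with markers of several classes were clustered again on 1000 genes and 15 components at resolution 0.5. A cluster was microglia-like where microglia markers were detected in at least 50% of its cells on average, and otherwise took the class, out of 19 marker lists, with the highest mean fold over all other cells (5 CPM added). It stayed unnamed with under 20 cells, under 3 markers detected in 10% of cells, own markers in under 20% of cells on average, or more of another class's markers among its top 10 genes. The 20% and 50% limits were set after the clusters were seen. The suffix -like marks classes named from transcripts alone.

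The mouse is the replicate. Counts were summed per mouse over the cells of a class and fitted with edgeR (quasi-likelihood F test, TMM scaling, filterByExpr by group) with terms for group and sex. All microglia comparisons come from 1 fit of the 24 mice, so they share its dispersion estimates (common biological coefficient of variation 13.6%), and comparisons that share a group are not independent. A gene passed at a Benjamini-Hochberg adjusted p < 0.05, two-sided. Differences in response between the sexes used a fit with 1 term for each group and sex. Other classes were tested where at least 4 mice of each group had 20 cells; with the main filter this held for neuroblast-like cells only, so T cell-, astrocyte-, endothelial-, neuroblast- and OPC-like cells were tested with the looser filter. CAM-like cells were not tested, as no mouse had 20.

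Gene lists of microglia (homeostatic, DAM, MHC class II, MHC class I, interferon response, complement, lysosome, cholesterol synthesis, lipid efflux and LXR targets, glycolysis, oxidative phosphorylation, NF-kB and cytokines, immediate early and dissociation stress, proliferation, phagocytosis, mitochondrially encoded and ribosomal genes) were tested with camera at the preset correlation of 0.01 on log2 CPM with a prior count of 2, and beside it with camera at an estimated correlation and with fry. Their p values were adjusted over the 17 lists within a comparison. A reactive astrocyte list and an endothelial activation list were tested in their own classes. Class shares and the DAM-high share were compared with exact two-sided permutation tests over mice, 924 assignments of 6 against 6, and for the interaction by permuting the isoform labels within uninduced and within induced mice.

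The genes named are, per microglia comparison, the 10 highest and 10 lowest log2 fold changes past the threshold with a mean of at least 10 CPM and a gene symbol, and up to 4 members of each list with the smallest p. For other classes and for sex 5 per side were taken, and Apoe, Cx3cr1, Trem2, Cst7, Itgax, Clec7a and Cd74 always. Genes outside this rule are marked as chosen after their values were seen. A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group. Genes that share sequence or overlap on the other strand are marked, since their reads can be assigned to the wrong gene.

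Microglia-like cells gave 0.86 to 5.92 M UMIs (M, 1e6) per mouse, which sets the precision. The fits were tested on simulated counts with the real means and library sizes, with 200 genes changed. For E3_T against E3_C edgeR recovered 44.8% of genes changed 1.5-fold, 89.4% at 2-fold and 98.5% at 4-fold, with 4 false calls among 157 (9256 genes). For E4_T against E4_C it recovered 41.5, 87.9 and 98.5%, with 8 false calls among 158 (9232 genes). With the run of titles as a term these fell to 3.1, 19.7 and 80.3% for E4_T against E4_C, and were 25.4, 75.8 and 92.3% for E3_T against E3_C. The interaction recovered 25.4, 68.2 and 92.3% of changes placed in E3_T and 20, 66.7 and 95.5% of those placed in E4_T. In astrocyte-like cells 27.3, 89.1 and 100% were recovered for E3_T against E3_C (7172 genes) and 25.4, 72.7 and 98.5% for E4_T against E4_C (7029 genes). With the interferon list shifted 1.5-fold, camera gave an adjusted p of 7.48e-18 (E3) and 1.21e-25 (E4) and called 0 and 1 of the other lists. The simulated genes vary independently, so this cannot tell how often lists of genes that move together are called falsely. In the real data the estimated correlation was 0.621 for the interferon list.

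Alternatives changed 1 choice at a time: RLE scaling, DESeq2, no filter on low counts, a mean of at least 10 CPM, a block by the number in the label, no sex term, the run of titles as a term, titles 1-8 alone, the 12 mice of a comparison alone, each sex alone, doublets kept, equal cells and UMIs per mouse, and each mouse left out in turn. Added after the data were seen were the looser filter, the looser filter with the run of titles, the run of titles crossed with sex, the median mitochondrial share as a term, and a fit without E3_T 1-M, 2-F and 2-M. A stricter filter, at least 1000 genes and under 5% mitochondrial UMIs, was planned but left 1 to 76 cells per mouse and was not run. Chance was judged from up to 100 splits of the same mice into groups of the same size. Libraries were checked for sex-linked reads and for identical counts.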

Results

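Cortex cells of 24 mice of an amyloid model were sequenced, 1 library per mouse. The mice form 4 groups of 6, each with 3 females and 3 males: E3_C and E4_C did not receive the inducer, and E3_T and E4_T received tamoxifen to induce apoE3 or apoE4 in microglia and central nervous system-associated macrophages (CAMs). The uninduced mice received no tamoxifen, so an effect of tamoxifen or of recombination is not separated from that of the isoform. Apolipoprotein E carries lipids between cells of the brain, and the E4 form raises the risk of Alzheimer's disease. The files hold 158,802 barcodes, 3590 to 9132 per mouse, with 6.36 to 20.07 M unique molecular identifiers (UMIs; M, 1e6) per mouse. The group means were 10.8 ± 2.73 M (SD) in E3_C, 10.1 ± 1.63 in E3_T, 14.4 ± 4.55 in E4_C and 10.4 ± 0.55 in E4_T. Within E4_C the 3 males held 17,073,785 to 20,069,316 UMIs and the 3 females 9,932,373 to 10,958,924. No library differed from its label in Xist and Y-linked reads, and no 2 libraries were identical.

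The cells are shallow and rich in mitochondrial reads. Median UMIs per barcode were 1065 to 1943, and the median mitochondrial share was 10.4 to 16.6%. The filter set before the data were examined, at least 500 genes and under 10% mitochondrial UMIs, kept 9.9 to 39% of the barcodes of a mouse, and 41,099 cells stayed after removal of doublets. The low yield differed between groups (28.2% in E3_C, 22.2% in E3_T, 34.4% in E4_C and 23.2% in E4_T). A looser filter, at least 200 genes and under 25% mitochondrial UMIs, kept 132,060 cells. The main filter is used unless the looser one is named.

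Nearly all kept cells are microglia-like. Classes were named from marker lists, and 38,729 cells (94.2%) fell to the microglia-like class, 586 to 2851 per mouse with 0.86 to 5.92 M UMIs. The other classes were small: 1077 neuroblast-like cells, 313 astrocyte-like, 184 monocyte-like, 183 OPC-like (oligodendrocyte precursors), 84 T cell-like, 68 endothelial-like and 43 CAM-like cells, with 290 unnamed. The looser filter gave 104,888 microglia-like cells (79.4%), 13,730 astrocyte-like, 5052 neuroblast-like, 2363 endothelial-like, 1988 OPC-like, 1279 T cell-like, 280 monocyte-like and 105 CAM-like cells. CAM-like cells, the 2nd target of the induction, numbered 1 to 11 per mouse there, too few for any test of their genes. Within microglia-like cells, cluster 3 held the largest share in all 4 groups, with 50.8 ± 7.46% in E3_C, 34.1 ± 19.5% in E3_T, 28.0 ± 4.76% in E4_C and 29.9 ± 3.74% in E4_T (mean ± SD of 6 mice). The 2nd largest was cluster 4 in E3_C (16.4%), cluster 8 in E3_T (24.4 ± 24.7%) and cluster 1 in E4_C (18.01%) and E4_T (20.19%). Cluster 8 is led by Cd74, H2-Ab1 and Cxcl13 and cluster 1 by Gpr84, Egr3 and Tnf. As several leading genes differ between the groups, sizes of clusters are not compared.

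No APOE transgene feature was analysed here, and mouse Apoe was almost silent in microglia-like cells of all groups. Apoe (chr7 19,696,109–19,699,188, mm10) had 11, 12, 12 and 11 counts in E3_C, E3_T, E4_C and E4_T, or 0.72, 0.98, 0.5 and 0.85 CPM (counts scaled to 1e6). Cdkn1a (chr17 29,090,976–29,100,727), which encodes the cell cycle inhibitor p21, separated induced from uninduced mice of both isoforms. It was 198 to 393 CPM in E3_T against 98.3 to 165 in E3_C, and 217 to 394 CPM in E4_T against 86 to 177 in E4_C. Genes next to the ROSA26 locus on chr6, a common site for transgenes, rose as well in E3_T and in E4_T, a set chosen after its values were seen. Gt(ROSA)26Sor (113,067,428–113,077,333) rose by log2 1.13 ± 0.21 in E3_T (adjusted p = 0.00482) and 1.24 ± 0.20 in E4_T (adjusted p = 0.00162), and Setd5 (113,077,365–113,153,435) by 0.64 ± 0.09 and 0.53 ± 0.09 (edgeR log2 fold change ± SE here and below). Thumpd3 (113,046,225–113,068,273) rose by 0.64 ± 0.12 and 0.43 ± 0.12, but it overlaps Gt(ROSA)26Sor on the other strand, so its reads are uncertain. Mtmr14, the next gene, did not pass.

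**Figure D1:**
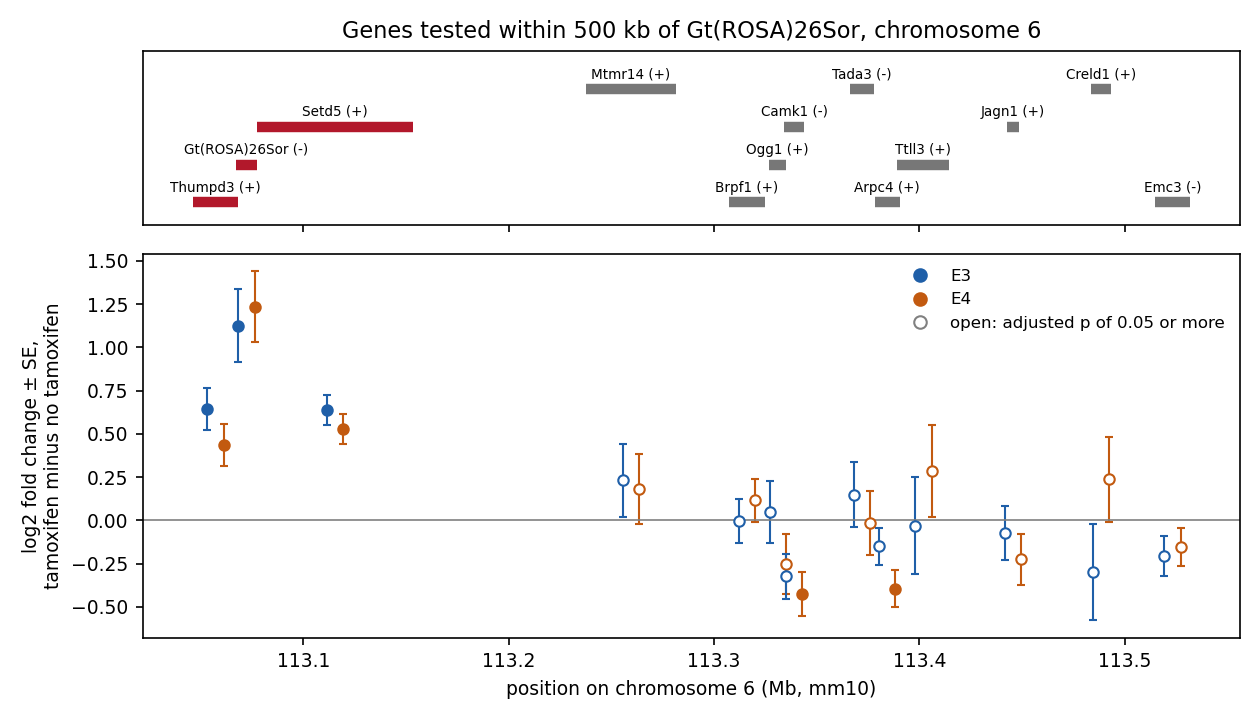
Change of the tested genes within 500 kb of Gt(ROSA)26Sor in microglia-like cells, in E3_T against E3_C and in E4_T against E4_C. Filled points passed adjusted p < 0.05 in edgeR.

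Microglia of the apoE3-induced mice showed a strong antigen presentation and interferon response, and most of it was carried by 3 of the 6 mice. In E3_T against E3_C, 127 of 9347 genes changed (98 higher, 29 lower; edgeR adjusted p < 0.05) and 59 of these by over 2-fold. The B cell chemokine Cxcl13 (chr5 95,956,951–95,961,068) rose most, 88.8-fold (log2 6.47 ± 1.06, adjusted p = 0.00299), from 2.88 ± 5.84 to 219 ± 198 CPM (mean ± SD). The MHC class II genes, which present peptides to CD4 T cells, followed: H2-Aa (chr17 34,282,744–34,287,823; 30.9-fold), H2-Eb1 (34,305,867–34,316,674; 30.4-fold), H2-Ab1 (34,257,689–34,269,419; 20.4-fold) and the invariant chain Cd74 (chr18 60,803,848–60,812,652; 21-fold, log2 4.39 ± 0.76, adjusted p = 0.00299). Cd74 was 821, 499 and 885 CPM in E3_T 1-M, 2-F and 2-M, but 8.87, 49.1 and 25.2 in E3_T 1-F, 3-F and 3-M, and 4.1 to 57.3 in all 21 mice other than the first 3. Of the 8 MHC class II genes measured, 4 rose over all genes tested, 0 fell and 4 did not pass, and 7 rose when adjusted over the list alone (camera adjusted p = 3.5e-09; adjusted p = 0.0489 with an estimated correlation).

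**Figure D2:**
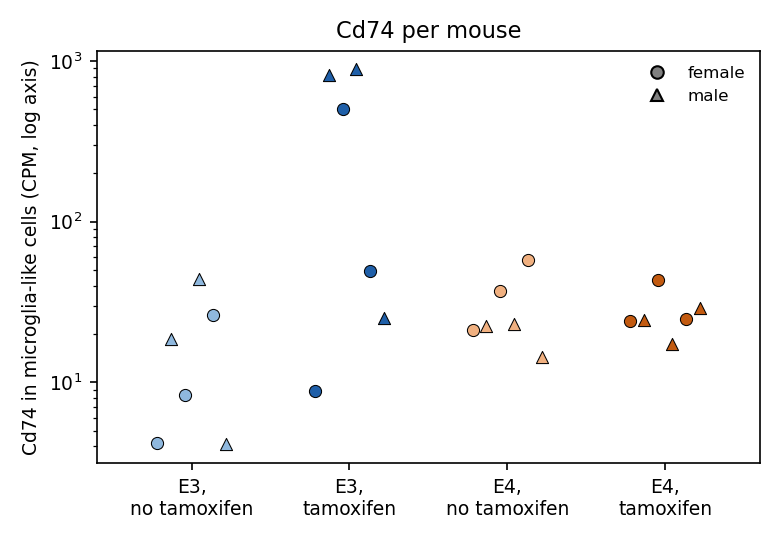
Cd74 in microglia-like cells of each mouse, in CPM on a log axis. Circles are females and triangles males.

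MHC class I and interferon-induced genes rose in the same comparison. H2-Q4 (2.43-fold, adjusted p = 0.00311) and H2-K1 (2.45-fold, adjusted p = 0.00717) present peptides to CD8 T cells, and B2m, their light chain, rose 1.65-fold (adjusted p = 0.0107; 0.051 without E3_T 2-M). H2-Q6 (8.14-fold) and H2-Q7 (6.64-fold) rose as well, though these near-identical paralogs share reads. Of 15 MHC class I genes 8 rose, 0 fell and 7 did not pass (12 rose over the list alone; camera adjusted p = 2.05e-12, 0.0677 with an estimated correlation). Of 39 interferon response genes 17 rose, 0 fell and 22 did not pass (36 rose over the list alone; camera adjusted p = 2.09e-28, 0.0642 with an estimated correlation). Among them Ifi204 (5.37-fold) and Ifi207 (6.3-fold), paralogs that sense DNA, and Phf11b (2.22-fold) rose. The monocyte chemokine Ccl12 rose 3.57-fold (adjusted p = 0.00401), and Plac8 (5.86-fold), a monocyte marker also seen in activated myeloid cells, and Fgl2 (5.2-fold) rose as well. Of the 3 monocyte markers measured in microglia-like cells 1 was higher in E3_T.

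Disease-associated microglia (DAM) genes rose in part, and homeostatic genes fell slightly. The phagocytic receptor kinase Axl (chr7 25,757,273–25,788,705) rose 7.85-fold from 1.9 to 17.5 CPM (adjusted p = 0.00555), and Cd52 rose 1.96-fold (adjusted p = 0.00523). Itgax (chr7 128,129,547–128,150,657; log2 1.84 ± 0.49, adjusted p = 0.0535), Cst7 (1.13 ± 0.56, adjusted p = 0.393) and Trem2 (−0.26 ± 0.12, adjusted p = 0.327) did not pass. Of 29 DAM genes 4 (Axl, Cd52, B2m and Lgals3bp) rose, 0 fell and 25 did not pass (7 rose over the list alone; camera adjusted p = 5.54e-06, 0.199 with an estimated correlation). The receptors Gpr34 (1670 to 1260 CPM, adjusted p = 0.00313) and P2ry12 (2630 to 2140 CPM, adjusted p = 0.0238), both high in resting microglia, fell, while the chemokine receptor Cx3cr1 (chr9 119,901,616–120,069,879; −0.18 ± 0.08, adjusted p = 0.29) did not pass. The call of P2ry12 was lost without E3_C 1-F (0.0748), E3_C 2-F (0.0505), E3_C 3-M (0.0516), E3_T 1-M (0.0573), E3_T 2-F (0.0603), E3_T 2-M (0.0706) or E3_T 3-F (0.0506). The integrin Itgam (log2 −0.32 ± 0.07, adjusted p = 0.00953), the cell cycle inhibitor Cdkn1c (−0.94 ± 0.19, adjusted p = 0.00778) and Tspan18 (−0.78 ± 0.15, adjusted p = 0.00523) fell too. Of 24 homeostatic genes 0 rose, 3 (Gpr34, P2ry12 and Sparc) fell and 21 did not pass (camera adjusted p = 5.61e-05, 0.0489 with an estimated correlation).

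Genes of energy supply and translation shifted by small amounts in E3_T. Of 40 oxidative phosphorylation genes 3 (Cox6a1, Cox7c and Cox8a) rose and 0 fell (camera adjusted p = 7.18e-10, 0.0677 with an estimated correlation). Cox7c, a subunit of cytochrome c oxidase, rose by log2 0.38 (adjusted p = 0.0142; 0.0539 without E3_T 2-M and 0.0535 without E3_C 3-M). Of 40 ribosomal protein genes 2 (Rps14 and Rps18) rose and 0 fell, and 25 rose over the list alone (camera adjusted p = 1.15e-13, 0.101 with an estimated correlation). Of 29 NF-kB and cytokine genes only the stress gene Gadd45b rose (adjusted p = 0.0422, but over 0.05 with any of 12 mice left out, up to 0.109 without E3_T 1-M; camera adjusted p = 4.45e-09, 0.0642 with an estimated correlation), and Tnf (adjusted p = 0.0647) and Ptgs2 (adjusted p = 0.0632) did not pass. The 20 glycolysis genes and 15 proliferation genes moved up as sets (camera adjusted p = 0.0452 for both, 0.499 and 0.473 with an estimated correlation), with no single gene past the threshold. Complement (adjusted p = 0.726), lysosome (0.857), cholesterol synthesis (0.648), lipid efflux (0.2), immediate early (0.169), phagocytosis (0.518) and mitochondrially encoded genes (0.0556) did not pass as sets.

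The size of the apoE3 response rests on few mice. The 8 mice of titles 1-8, 4 E3_T and 4 E3_C, gave 216 genes. Of these 4 E3_T mice 3 are 1-M, 2-F and 2-M, the mice with high Cd74, so this is no independent support for the call. There Cd74 rose by log2 4.91 ± 0.68 (adjusted p = 0.000674), Axl by 3.6 ± 0.47 and Cdkn1a by 1.32 ± 0.17 (adjusted p = 0.000487 for both). Without E3_T 1-M, 2-F and 2-M, a choice made after the values were seen, 2 genes passed, Setd5 (adjusted p = 0.0358) and Myc (adjusted p = 0.0358), and Cd74 did not (adjusted p = 0.754). As sets, interferon (camera adjusted p = 0.000837) and MHC class II genes (0.0329) still passed there, though not with an estimated correlation (0.638 and 0.511), and MHC class I (0.171) and DAM genes (0.356) did not. Leaving out 1 mouse gave 51 genes without E3_C 3-M, 53 without E3_T 2-M, 60 without E3_T 1-M, 69 without E3_C 1-F, 73 without E3_T 2-F and 226 without E3_T 1-F. Cxcl13, Cd74, H2-Aa, H2-Ab1, H2-Eb1, Axl, Ccl12, Cdkn1a and Gt(ROSA)26Sor stayed past the threshold each time.

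Microglia of the apoE4-induced mice changed mostly by under 2-fold. In E4_T against E4_C, 628 of 9347 genes changed (227 higher, 401 lower), 43 of them by over 2-fold. All E4_C mice lie in titles 9-16 and all E4_T mice in titles 17-24, so this comparison coincides with the run of titles. Cdkn1a rose most surely, 2.48-fold from 123 ± 31.8 to 302 ± 71.6 CPM (log2 1.31 ± 0.17, adjusted p = 0.000256). The lipid sensor and phagocytic receptor Trem2 (chr17 48,346,401–48,354,147) fell from 1380 ± 218 to 856 ± 77.6 CPM (log2 −0.68 ± 0.12, adjusted p = 0.00171), and all E4_T mice (743 to 950) lay below all E4_C mice (1120 to 1730). Both genes kept this call with each mouse left out. Trem2 also stood higher in E4_C than in E3_C, so its fall started from a raised level. With the run of titles as a term, Cdkn1a (log2 2.19 ± 0.37, adjusted p = 0.0227) was the only gene past the threshold, chosen after its values were seen, and Trem2 (−0.22 ± 0.24, adjusted p = 0.946) was not.

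**Figure D3:**
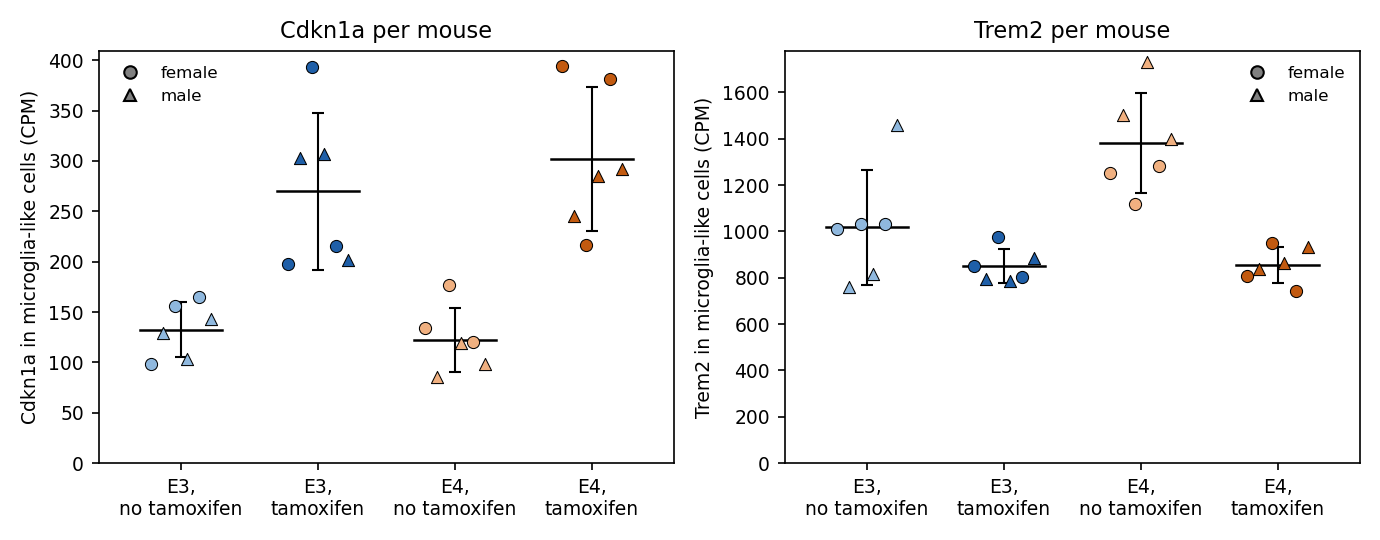
Cdkn1a and Trem2 in microglia-like cells of each mouse, in CPM. Bars are the mean and SD of 6 mice.

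Further genes that rose in E4_T belong to several processes. Cxcl13 rose 18.2-fold from 2.59 to 54.4 CPM (log2 4.18 ± 1.04, adjusted p = 0.0152), but not without E4_T 1-M (log2 3.36; adjusted p = 0.0904). Top2a (chr11 98,992,943–99,024,189), a marker of dividing cells, rose 2.98-fold (adjusted p = 0.0203), but not without E4_C 1-M (0.0557), E4_C 3-M (0.0605) or E4_T 3-M (0.0741). The DAM gene Spp1 (chr5 104,435,118–104,441,050) had a log2 fold change of 2.19 ± 0.67 (adjusted p = 0.0456), which rests on 1 mouse (0.9 without E4_T 1-F; adjusted p = 0.494) and was lost without E4_C 1-M (0.0938), 2-M (0.0631), 3-M (0.0859), 1-F (0.066), 2-F (0.0902), E4_T 1-M (0.0641), E3_C 2-M (0.0506), E3_C 3-F (0.05) or E3_T 1-M (0.0513) as well. The lipid exporter Abca1 rose by log2 0.37 ± 0.08 (adjusted p = 0.00689) and the glycolytic enzyme Hk2 by 0.46 ± 0.11 (adjusted p = 0.00932). Of 40 oxidative phosphorylation genes 9 rose, 2 fell and 29 did not pass (camera adjusted p = 0.0488, 0.904 with an estimated correlation), with Ndufb2 at log2 0.6 ± 0.1 (adjusted p = 0.00162) and Atp5d at −0.77 ± 0.14 (adjusted p = 0.00279). Of 15 proliferation genes Top2a alone rose (camera adjusted p = 0.0032, 0.805 with an estimated correlation).

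In E4_T the protease inhibitors Timp2 (log2 −0.57 ± 0.11, adjusted p = 0.00279) and Cst3 (−0.41 ± 0.09, adjusted p = 0.00625) fell, as did the immunoproteasome subunit Psmb8 (−0.68). Pmvk of cholesterol synthesis (−1.18 ± 0.22, adjusted p = 0.00294), Gapdh (−0.66), the antioxidant enzyme Sod2 (−0.58) and the ribosomal Rpl3 (−0.79) fell. So did Rapsn (−1.3 ± 0.19, adjusted p = 0.00142), Upk1b (−1.36), Eif6 (−1.19) and Psmc4 (−1.13). All of these kept their call with each mouse left out. None of them passed with the run of titles as a term, and Psmb8 (0.52) and Gapdh (0.01) turned upward. Cacna1a (chr8 84,388,440–84,640,246), a calcium channel subunit, fell from 19.2 to 5.5 CPM (log2 −1.92 ± 0.52, adjusted p = 0.0242), but its call was lost without E4_C 1-M (0.0527), 2-M (0.0793), 3-M (0.052) or E4_T 1-M (0.0778), 2-M (0.0728), 3-M (0.0659).

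No MHC gene rose past the threshold in apoE4-induced microglia. Of 8 MHC class II genes 0 rose and 0 fell (median log2 −0.52; camera adjusted p = 0.19), and of 15 MHC class I genes 0 rose and the immunoproteasome subunits Psmb8 and Psmb10 fell (adjusted p = 0.69). With the run of titles as a term the MHC class II (adjusted p = 0.00626), MHC class I (4.38e-07), DAM (9.12e-07), complement (0.0204), lysosome (0.017), glycolysis (0.0137) and ribosomal sets (0.00674) changed direction and passed. The term corrects this comparison by a run difference taken from the E3 mice alone. E3_T 1-M, 2-F and 2-M, with their high MHC values, lie in titles 1-8 and pull that difference. The upward turn of the MHC sets carries their values over and cannot be read as a result of E4_T. The 39 interferon genes shifted upward as a set (median log2 0.46; camera adjusted p = 1.55e-05, 0.904 with an estimated correlation), but 0 passed singly, and Ccl12 (1.0 ± 0.32, adjusted p = 0.0567) came close. Of 29 DAM genes Spp1 rose and Trem2 and Timp2 fell (adjusted p = 0.973), and of 24 homeostatic genes Selplg rose and Cst3 and Sparc were among those that fell (adjusted p = 0.69). Complement genes split, with C5ar1 and C5ar2 higher and C1qa and C1qb lower (adjusted p = 0.87 for the set). Of 40 ribosomal genes 2 rose and 8 fell (adjusted p = 0.87), of 14 cholesterol synthesis genes Pmvk and Ebp fell (adjusted p = 0.139), and of 45 lysosome genes Grn rose and Ctss and Npc2 were among those that fell (adjusted p = 0.368). Lipid efflux (adjusted p = 0.296), glycolysis (0.83), NF-kB (0.87), immediate early (0.26), phagocytosis (0.471) and mitochondrially encoded genes (0.368) did not pass as sets. The call of C1qb was lost without E4_C 1-M, 2-M or 3-M or E4_T 1-M or 3-M, and that of C1qa with any of 15 mice left out. C1qa (0.35), C1qb (0.22), Ctss (0.34), Npc2 (0.23), Psmb8 (0.52) and Psmb10 (0.35) turned upward and Selplg (−0.14) downward with the run of titles as a term, none past the threshold.

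**Figure D4:**
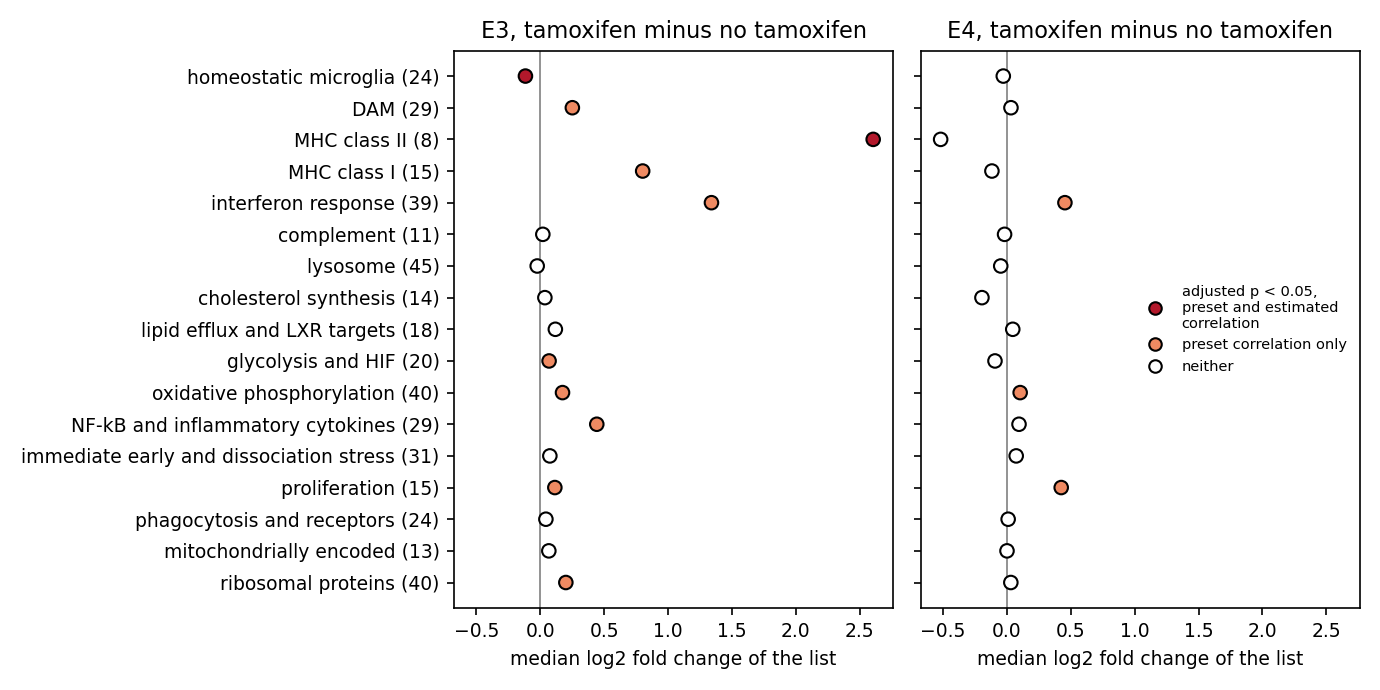
Median log2 fold change of 17 gene lists in microglia-like cells, for E3_T against E3_C and E4_T against E4_C. Dark points passed camera with the preset and the estimated correlation, light points with the preset alone, and open points with neither.

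The apoE4 count depends on the fit. DESeq2 gave 685 genes, the mice of the comparison alone 908, and a term for the median mitochondrial share 656. Without the sex term 298 genes passed, and with the looser filter 1375, 566 of the 628 among them. With equal cells and UMIs per mouse 94 passed, 89 of the 628 among them. Microglia-like cells of E4_C held 24,148,165 UMIs and those of E4_T 12,910,169. With the run of titles as a term 1 gene was left, and there the median SE of the 628 genes rose from 0.13 to 0.29. Leaving out 1 mouse gave 282 genes without E4_T 1-M, 332 without E4_C 2-M, 354 without E4_T 3-M, 373 without E4_C 1-M and 381 without E4_C 3-M.

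The 2 inductions share a small set of genes. Of the genes past the threshold in both isoforms, whose comparisons have no library in common, 15 were higher in both (2.38 expected by chance), 9 lower in both (1.24 expected) and 0 opposite. The shared higher genes are Ccnd1, Cd34, Cdkn1a, Cox7c, Cox8a, Cxcl13, Glipr1, Gt(ROSA)26Sor, Ints9, Pmaip1, Rnase6, Rps18, Setd5, Thumpd3 and Tnfaip2. The shared lower genes include the matrix protein Sparc, Thrsp, Hspb3 and Eva1b. Within titles 1-8, 11 of the 23 shared genes tested there passed in E3_T against E3_C, and all 23 kept their direction, though 8 of the 12 mice of the comparison are the same. Of the 24 genes 6 passed in E3_T and 1, Cdkn1a, in E4_T with the run of titles as a term.

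No single gene was shown to respond differently to apoE4 than to apoE3. The interaction, (E4_T − E4_C) − (E3_T − E3_C), gave 0 genes in edgeR, with 850 at unadjusted p < 0.05, 19 in DESeq2 and 239 in edgeR without the filter on low counts. Mmp2, a matrix protease, came closest: it fell in E3_T from 19.4 to 11.1 CPM (log2 −0.8 ± 0.18, adjusted p = 0.0263) and went from 12.7 to 19.1 CPM in E4_T (0.53 ± 0.17, adjusted p = 0.0564), an interaction of 1.33 ± 0.25 (adjusted p = 0.0837, and 0.00417 in DESeq2). With the run of titles as a term Mmp2 was the only gene past the threshold (2.13 ± 0.32, adjusted p = 0.00325), chosen after its values were seen. H2-Ab1 (−5.13 ± 1.11, adjusted p = 0.105), Cd74 (−4.57 ± 1.08, adjusted p = 0.158), H2-Eb1 (−6.26 ± 1.55) and H2-Aa (−5.74 ± 1.47, adjusted p = 0.189 for both) did not pass in edgeR, and Cd74 did in DESeq2 (adjusted p = 0.0342). Trem2 had an interaction of −0.43 ± 0.16 (adjusted p = 0.413). Leaving out E3_C 3-M gave 15 genes and leaving out E3_T 3-M gave 18. The fall of Mmp2 in E3_T was lost without E3_C 3-M (0.0774), E3_T 3-M (0.0562) or E3_T 3-F (0.0529). Its interaction passed without E3_C 3-M (0.0364), E3_T 3-M (0.0318) or E4_T 2-M (0.0189), and H2-Ab1 and Cd74 passed without E3_T 3-M (0.0318).

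As sets, MHC genes had a lower response in E4 than in E3 with the preset correlation, but not with an estimated one. All 8 MHC class II genes had a lower response in E4 over the list alone (median log2 −2.99; camera adjusted p = 5.37e-10, 0.0626 with an estimated correlation), as did 13 of 15 MHC class I genes (camera adjusted p = 5.37e-10, 0.152 with an estimated correlation). Interferon (1.78e-06; 0.521 with an estimated correlation), DAM (0.000177; 0.367), NF-kB (1.5e-05; 0.193), ribosomal (5.37e-10; 0.231), cholesterol synthesis (0.0238; 0.134) and oxidative phosphorylation genes (0.0157; 0.576) were lower, and homeostatic genes higher (0.0115; 0.152). With the run of titles as a term the MHC class II (adjusted p = 0.0531), MHC class I (0.179), NF-kB (0.0538), cholesterol synthesis (0.16) and homeostatic sets (0.179) did not pass, the interferon set turned upward past the threshold (0.0252), and the DAM set turned upward without passing (0.397). That term takes in the values of E3_T 1-M, 2-F and 2-M, so these turns cannot be read as a result of E4. Without E3_T 1-M, 2-F and 2-M the MHC class II set passed (adjusted p = 0.00104), while MHC class I (0.0792), DAM (0.634), NF-kB (0.0759), cholesterol synthesis (0.0792), oxidative phosphorylation (0.27) and homeostatic sets (0.27) did not, and the interferon set turned upward without passing (0.27). Complement (adjusted p = 0.764), lysosome (0.254), glycolysis (0.0547) and proliferation genes (0.179) did not pass, nor did lipid efflux, immediate early, phagocytosis and mitochondrially encoded genes (adjusted p = 0.764 for each).

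E4 and E3 mice without tamoxifen differed in many genes. In E4_C against E3_C, 400 genes differed (223 higher, 177 lower; 94 by over 2-fold). Ifi44 (chr3 151,730,922–151,749,960), an interferon-induced gene, had 0 counts in all E3_C mice and 909 in E4_C (37.6 CPM), at least 190-fold. It also had 47 counts in E3_T, 16 in 1-M, 18 in 2-F and 13 in 2-M. Slc1a3 (chr15 8,634,124–8,710,764), a glutamate transporter, was 7.43-fold higher in E4_C (log2 2.89 ± 0.17, adjusted p = 9.04e-13), and so was its neighbour Ranbp3l (8,967,949–9,067,335; log2 2.37). Tpm3-rs7 had a log2 difference of 3.98 ± 0.16, though this tropomyosin copy shares reads with Tpm3. Of the NF-kB and cytokine list Tnfaip3, a brake on NF-kB (log2 1.07, adjusted p = 4.8e-06), Ccrl2 (1.41) and Icam1 (0.56) were among those higher in E4_C. The microglial gene Fcrls (−1.62) was lower.

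DAM genes stood higher in E4_C than in E3_C. Of 29 DAM genes 8 were higher, 0 lower and 21 not past the threshold (12 over the list alone; camera adjusted p = 2.49e-10, 0.133 with an estimated correlation). Ctsl (log2 0.6 ± 0.1, adjusted p = 0.000561) and the signalling adaptor Tyrobp (0.4) kept their calls with each mouse left out. So did S100a6 (3.25), which is not on the DAM list. Cst7 (chr2 150,570,415–150,578,944) stood at 47.1 against 10.7 CPM (log2 1.96 ± 0.5, adjusted p = 0.0206), but not past the threshold without E3_C 1-F (0.0563), E3_C 1-M (0.0554), E3_C 2-M (0.06) or E4_C 2-M (0.0834). Of 29 NF-kB genes 12 were higher and 0 lower (camera adjusted p = 9.69e-13, 0.0663 with an estimated correlation), and of 40 ribosomal genes 16 were higher and 0 lower (1.42e-22, 0.085 with an estimated correlation). MHC class II (0.00357; 0.332 with an estimated correlation), oxidative phosphorylation (0.00284; 0.522) and immediate early genes (0.000382; 0.303) were higher as sets. Homeostatic genes were not lower as a set (adjusted p = 0.061; 4 of 24 lower), and the other 10 lists did not pass. The count was 446 in DESeq2, 60 with the run of titles as a term, and 250 without E3_C 1-M, 260 without E3_C 2-M and 617 without E3_C 3-M.

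Part of the differences between E4 and E3 was also found between the induced mice. In E4_T against E3_T, 353 genes differed (173 higher, 180 lower; 134 by over 2-fold). Tpm3-rs7 (log2 4.16 ± 0.17), Ifi44 (3.98 ± 0.59, adjusted p = 0.00026), Slc1a3 (2.73 ± 0.17, adjusted p = 3.65e-12), Tnfaip3 (1.08 ± 0.13) and Bcl2a1d (1.78) were higher in E4_T, with the immediate early genes Fos (0.62 ± 0.09, adjusted p = 0.000183) and Dusp1 (0.61). Cd74 (−3.81 ± 0.75, adjusted p = 0.0028), H2-Ab1 (−4.65 ± 0.79), H2-Aa (−5.66), H2-Eb1 (−6.1) and the interferon gene Ifi204 (−1.87) were lower in E4_T. Of 15 MHC class I genes 8 were lower (camera adjusted p = 1.21e-07, 0.342 with an estimated correlation), and of 8 MHC class II genes 4 (0.000292, 0.342 with an estimated correlation). Immediate early genes were higher (7 of 31; 0.00081, 0.415 with an estimated correlation), as were NF-kB (0.0165; 0.657) and ribosomal genes (0.00293; 0.657), and interferon (0.00309; 0.689) and glycolysis genes (0.00578; 0.592) were lower. Without E3_T 1-M, 2-F and 2-M the interferon set turned upward past the threshold (0.000241). The MHC differences did not hold there (0.625 for class II and 0.639 for class I). The run of titles as a term gave the same (0.000618, 0.536 and 0.745). As none of these mice shares a run with E4_T, this is no separate test. DAM genes did not pass (adjusted p = 0.0786; Fabp5 and Igf1 higher), but passed as higher under these 2 settings (0.0001 and 1.03e-06), nor did the other 9 lists. The count was 390 in DESeq2, 77 with the run of titles as a term, 112 without E3_T 1-M, 2-F and 2-M, and 210 without E4_T 1-M, 220 without E3_T 2-F, 223 without E3_T 2-M and 228 without E3_T 1-M. Of the 400 genes of the uninduced and the 353 of the induced mice 112 differed between E4 and E3 in the same direction in both, 63 higher and 49 lower (4.13 and 3.41 expected by chance).

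The share of microglia with a DAM-high profile was higher in E3_T than in E3_C. A DAM-high cell holds more counts over the DAM list than the 90th percentile of uninduced cells, with each cell thinned to 1000 UMIs, and 7.7% of cells lay within 1 count of this limit. They made up 5.74 ± 2.31% of microglia in E3_C and 13.9 ± 7.01% in E3_T (mean ± SD; two-sided exact permutation test, p = 0.0108, adjusted p = 0.027; p = 0.0286 within titles 1-8, where 3 of the 4 E3_T mice are 1-M, 2-F and 2-M). E4_C started higher at 12.3 ± 4.1% (against E3_C, exact permutation test, p = 0.00433, adjusted p = 0.0216), and E4_T stood at 11.2 ± 2.9% (p = 0.613). The response differed between isoforms by −9.33 percentage points (two-sided permutation test, p = 0.0166, adjusted p = 0.0277), and the difference between E4_T and E3_T did not pass (−2.76 points; p = 0.418). E3_T ranged from 6.57% (3-M) to 25.3% (2-F), and without 1-M, 2-F and 2-M E3_T against E3_C did not pass (permutation test, p = 0.131, adjusted p = 0.179). At 2000 UMIs none of the 3 passed (adjusted p = 0.216, 0.275 and 0.39), nor with the looser filter did E3_T against E3_C (0.0703) or the interaction (0.0848).

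**Figure D5:**
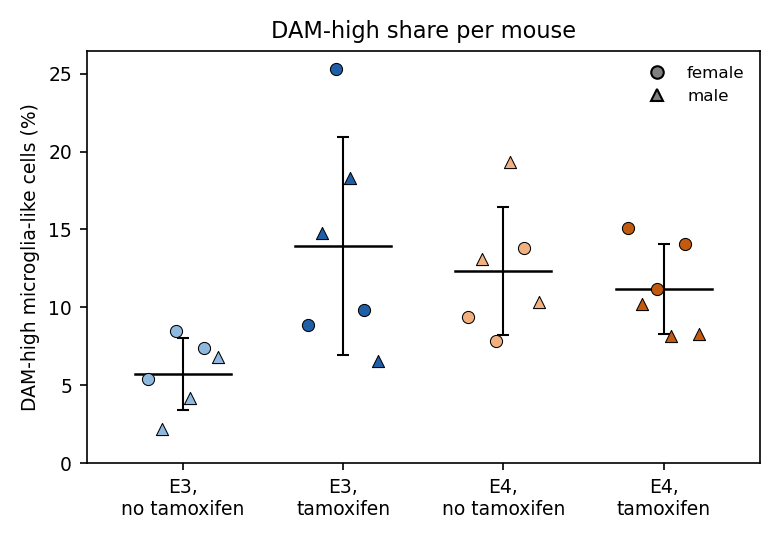
Percent of microglia-like cells with a DAM-high profile in each mouse, at equal UMIs per cell. Bars are the mean and SD of 6 mice.

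Males differed from females in 1262 genes (729 higher, 533 lower), 39 of them by over 2-fold. This compares 12 mice with 12 and each induction 6 with 6, so the counts cannot be ranked. With equal cells and UMIs per mouse 380 genes passed, 343 of the 1262 among them. The kinase Dclk1 (log2 1.83) and the transporter Slc15a3 (1.39) were higher in males, and Slc12a3 (−1.41) and the sphingolipid enzyme Degs2 (−1.2) in females. The response to induction differed between the sexes in 3 genes, all with a lower response in males: the transcription factor Cebpb (−0.93 ± 0.16), Pebp1 (−0.82 ± 0.14) and the metabolic regulator Txnip (−0.56 ± 0.1, adjusted p = 0.0179 for each), chosen after their values were seen. DESeq2 gave 48 genes, a term for the median mitochondrial share 88, no filter on low counts 156, the looser filter 33, the run of titles as a term 20, and equal cells and UMIs 2, and 21 passed without E3_T 1-M, 2-F and 2-M. The edgeR count moved to 0 without E3_C 2-F, E4_C 1-F or E4_T 1-M, 5 without E3_C 1-F, 7 without E3_C 2-M or E4_T 3-F, 8 without E3_C 3-F and 23 without E4_T 2-M. Within E3 the sexes differed in 0 genes (edgeR; 477 at unadjusted p < 0.05, 0 in DESeq2 and 31 without the filter on low counts). Within E4 they differed in 40 (19 higher, 21 lower), a count that moved to 83 without E3_C 3-M, to 21, 22, 11, 12, 26 and 11 without E4_C 1-M, 2-M, 3-M, 1-F, 2-F and 3-F, and to 6, 89, 10, 25, 15 and 24 without E4_T 1-M, 2-M, 3-M, 1-F, 2-F and 3-F. With the median mitochondrial share as a term 141 genes passed there, 15 of the 40 among them, and with equal cells and UMIs per mouse 8 passed, 6 of the 40 among them. The median mitochondrial share of the kept microglia-like cells, which is this term, was 7.57 to 7.8% in E4_T females and 6.7 to 6.85% in E4_T males. In females alone E3_T against E3_C gave 5 genes, St8sia6, Cxcl13, Thumpd3, Gt(ROSA)26Sor and Axl, chosen after their values were seen, and 10 in males, and E4_T against E4_C gave 30 and 460.

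Other cell classes could be tested for few genes, mostly with the looser filter. T cell-like cells of E3_T, from 437 genes, had 11 changed (9 higher, 2 lower), with the chemokines Ccl3 (log2 2.5 ± 0.54, adjusted p = 0.00987) and Ccl4 (1.73 ± 0.48), the lymphocyte receptor genes Klrd1 (1.94 ± 0.38) and Cd8a (1.74 ± 0.41) and the nuclear receptor Nr4a2 (2.09 ± 0.42) higher. Ccl4 was 3500 to 6420 CPM in microglia-like cells of E3_T against a mean of 3130 in their T cell-like cells, so RNA of microglia can add to it. None passed with the run of titles as a term or without E3_T 1-M, 2-F and 2-M, and in E4_T 0 of their genes passed (67 at unadjusted p < 0.05). Astrocyte-like cells changed in 18 genes in E4_T (10 higher, 8 lower), with Nupr1 (−1.11 ± 0.19, adjusted p = 0.0125) and the small heat shock gene Cryab (−0.81 ± 0.17) lower, but in 0 in E3_T (321 at unadjusted p < 0.05) and 0 in the interaction (499). Endothelial-like cells changed in 23 genes in E4_T (16 higher, 7 lower), with the matrix gene Ctgf (1.37 ± 0.29) higher and the stress gene Ubb (−0.95 ± 0.17, adjusted p = 0.00786) lower, and in 0 in E3_T (255). Their interaction gave 2 genes, among them the microglial gene C1qa (−1.93 ± 0.39, adjusted p = 0.0341), chosen after its value was seen. Neuroblast-like cells changed in 222 genes in E4_T (148 higher, 74 lower), led by the histone gene Hist1h4h (1.56 ± 0.24, adjusted p = 0.000414), and in 0 in E3_T (441) and the interaction (287). With the main filter 3 of their genes fell in E4_T, Itm2b (−1.28 ± 0.22), Rpl3 (−0.95 ± 0.17) and Eif3f (−0.94 ± 0.21), chosen after their values were seen, and 0 in E3_T (120) and the interaction (91). OPC-like cells had 0 genes in E3_T (116), E4_T (191) and the interaction (131). None of these E4_T calls of astrocyte-, endothelial- or neuroblast-like cells with the looser filter passed with the run of titles as a term.

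Reactive lists of the other classes did not pass. The A1 and reactive list of astrocyte-like cells did not pass in E3_T, E4_T or the interaction (median log2 0.14, 0.42 and 0.1; camera adjusted p = 0.0928, 0.106 and 0.677), nor did the activation list of endothelial-like cells (median log2 0.05, 0.1 and 0.07; adjusted p = 0.871, 0.256 and 0.472). Over the list alone 1 astrocyte gene rose in E3_T and 1 in E4_T, and 1 endothelial gene in E4_T and 1 in the interaction. Some markers of other classes changed within microglia-like cells. Of 3 monocyte markers 1 rose in E3_T and 1 in E4_T (median log2 0.092 and 0.947), of 4 astrocyte markers 0 changed in E3_T and 1 fell in E4_T (−0.326 and −0.243), and of 2 B cell markers 0 changed in E3_T and 1 fell in E4_T (−0.187 and −0.435). The 2 erythroid markers had median log2 values of −4.201 in E3_T and −2.477 in E4_T, with neither past the threshold. The measured markers of CAMs (1), neutrophils (1), endothelium (1) and oligodendrocytes (2) did not pass in E3_T or E4_T.

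No class share passed, but between groups no lone class could: the lowest possible p, 0.00216, adjusts to 0.151 over 70 tests. With the looser filter T cell-like cells were 2.23 ± 1.66% in E3_T against 0.505 ± 0.15% in E3_C (exact permutation test, p = 0.00433, adjusted p = 0.152; p = 0.0286 within titles 1-8). They made up 2.7, 4.27 and 4.01% in E3_T 1-M, 2-F and 2-M, all in titles 1-8 and high in Cd74, and 0.151 to 0.93% in the other 21. Endothelial-like cells were 2.76 ± 0.68% in E4_T against 1.29 ± 0.37% in E3_T (permutation test, the lowest possible p). CAM-like cells were 0.045 ± 0.01% in E3_T against 0.126 ± 0.07% in E3_C (permutation test, p = 0.0173, adjusted p = 0.295).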

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

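All tests of explanations in this part, the comparison with other splits of the mice included, were written down only after the result was seen. Each count of splits is out of 100 with the real grouping included, so 1 is the smallest possible.

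The MHC class II response is present in 3 mice of 1 group. Cd74 reached 499 to 885 CPM in E3_T 1-M, 2-F and 2-M, and at most 57.3 in the other 21 mice. T cell-like cells were more frequent in the same 3 mice, at 2.703 to 4.272% of cells with the looser filter against 0.151 to 0.93% in the other 21. Free RNA from other cells is excluded as the source, as at equal depth a Cd74 UMI was found in at most 2.3% of astrocyte-like cells of these mice and in at least 26.9% of their microglia-like cells. A difference of the run of titles 1-8 is excluded too, since the other 5 mice of the run had at most 43.9 CPM. That E3_T 1-F, 3-F and 3-M received no tamoxifen or are mislabelled is not borne out by Cdkn1a, which was at least 198 CPM in them against at most 165 in E3_C. How much apoE3 each mouse made was not analysed here, and why only 3 of 6 show the response was not tested.

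The 628 genes that changed in E4_T against E4_C cannot be told apart from a difference between titles 9-16 and 17-24. The run difference, estimated from E3 mice alone, had the sign of the E4_T difference in 82.8% of the 628 genes and in 59.1% of the other genes, so the run could contribute to many of them, although the E3 estimate takes in E3_T 1-M, 2-F and 2-M. That estimate itself called 0 genes (edgeR; 889 at unadjusted p < 0.05). Of the 628 genes 60.2% had the same sign in E3_T against E3_C within titles 1-8, a comparison inside 1 run, against 52.8% of the other genes. Induction of apoE4 as the cause cannot be judged, as only 1 gene passed with the run of titles as a term and that term rests on E3 mice. A term for the mitochondrial share of kept cells left 656 genes, with 574 of the 628. As E4_C and E4_T overlap in this share (7.04 to 7.58% and 6.7 to 7.8%), cell quality stays open (yield 34.4 and 23.2%). Of the 24 genes that changed in both isoforms a run difference alone is excluded for 1, Cdkn1a, which passed in both with the run as a term. With the term E3_T against E3_C rests on titles 1-8, whose mice helped choose the genes, so it is no separate test. All 24 kept their sign, median size went from log2 0.62 to 0.58 and median SE from 0.13 to 0.16. On the E4 side all 24 kept their sign too, but size went from 0.63 to 0.44 and SE from 0.13 to 0.29. There the other 23 cannot be told from a run difference.

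The 112 genes that differ between E4 and E3 in both uninduced and induced mice were tested with the run of titles as a term. In both comparisons 19 passed, Slc1a3, Ranbp3l, Ifi44 and Tnfaip3 among them, which excludes a run difference alone for these. The other 93 did not pass in both and singly stay open. All 112 kept their sign in E4_C against E3_C and 111 in E4_T against E3_T. Median sizes went from log2 0.99 to 0.84 and from 1 to 0.99. Median SEs rose from 0.18 to 0.25 and from 0.19 to 0.28. The calls thus ended more through larger spread than smaller differences. As sets the differences between E4 and E3 do not come from runs alone. Of the 400 genes of E4_C against E3_C 82.8% had the same sign in E4_T against E3_T within titles 17-24, mice that did not choose the genes, against 54.7% of the other genes (median log2 0.28, median SE 0.17, 0.57 in the choosing mice). Of the 353 genes of E4_T against E3_T 86.7% had the same sign in E4_C against E3_C within titles 9-16, against 57.5% of the other genes (0.3, SE 0.16, and 0.8). The smaller size there leaves room for a part from runs or from the choice of genes. Linked variants that differ between the E3 and E4 mice may explain part of the 112: 29 of their 96 named genes lie within 1 Mb of another, against a median of 14 in random sets (one-sided permutation test over 10,000 sets, p = 0.0017). The genes of E4_T against E4_C, both E4, lie close together as well, though by less (361 of 600, median 336 in random sets, one-sided permutation test over 2000 sets, p = 0.032), so closeness is not specific to variants. Leaky expression of the isoforms without tamoxifen was not tested.

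Counts of changed genes in microglia-like cells were compared with other splits. For E3_T against E3_C, 4 of 100 splits gave at least the 127 genes (highest other 181), so chance is excluded at the 5% level only narrowly. Chance is excluded for E4_T against E4_C (628 genes; 1 split, highest other 43), E4_T against E3_T (353; 1, 313), E4_C against E3_C (400; 1, 329) and males against females (1262; 1, 2). In the E4_T against E3_T splits the highest other count was 313 with E3_T 1-M, 2-F and 2-M on 1 side and 9 with them apart. For E3_T against E3_C these were 181 and 128. The 353 genes of E4_T against E3_T thus depend largely on where these 3 mice fall. For the interaction 0 genes passed, so all 100 splits gave as many (highest other 252) and this count tests nothing about chance. Chance cannot be excluded for its 850 genes with an unadjusted p < 0.05 (8 splits; highest other 1725). The counts of lists called can arise by chance in each comparison: 10 in E3_T against E3_C (16 splits; highest other 13), 3 in E4_T against E4_C (53; 9), 9 in the interaction (10; 13), 7 in E4_T against E3_T (12; 10) and 6 in E4_C against E3_C (35; 12).

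Interactions with induction stood out. The interaction moved 9 gene lists and the DAM-high share (−9.33 points), but no list passed with an estimated correlation (0.0626 to 0.576), and the share did not at 2000 UMIs (0.39) or with the looser filter (0.0848). The response differed between the sexes in 3 genes, which chance can give (18 splits; highest other 32), and within E4 in 40 genes. For this count (3 splits; highest other 54) chance is excluded at the 5% level only narrowly, and not for its 1077 genes at unadjusted p < 0.05 (5; 1322). Of these 40 only 15 passed with the median mitochondrial share as a term, so RNA quality stays open. In endothelial-like cells 2 genes, among them the microglial C1qa, differed in response (1 split; highest other 1).

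In other classes, uncorrected for the counts tested, chance is excluded at the 5% level. This holds only narrowly for 3 neuroblast-like genes in E4_T with the main filter (4 splits; highest other 26). With the looser filter 11 T cell-like genes in E3_T are as narrow (4; 40). Its E4_T counts were 18 in astrocyte- (1; 2), 23 in endothelial- (1; 4) and 222 in neuroblast-like cells (1; 42). Splits do not test the run, which coincides with E4_T.

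Single mice lay far from the others of their group in 15 of 224 sets of values checked by Dixon's Q at 0.625, where 11.2 are expected by chance. Of these E3_C 3-M accounts for 6: endothelial-like cells with the looser filter (2.74% against 1.23% in the next mouse), Eif6 (22.6 against 12.3 CPM), Eva1b (34.9 against 26), Fam212a (59.0 against 38.2), Rapsn (79.8 against 58.2) and Rnh1 (63.1 against 34.6). In E3_C 2-M Cxcl13 was 14.8 against 1.14 CPM, in E4_T 1-M 174 against 62.7 and in E4_T 2-M Eif6 was 10.5 against 6.48. Top2a was 24.6 against 6.54 CPM in E4_C 2-F and 32.4 against 20.1 in E4_T 3-M. Ctla2b was 32.7 against 21.3 CPM in E3_T 2-F, Fgl2 53.1 against 36.7 in E4_T 1-F, and endothelial-like cells 2.0% against 1.39% in E3_T 3-F. Gt(ROSA)26Sor was low in E4_C 2-M, 8.66 against 12.6 CPM.

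A signal outside the named classes came from 1 mouse. Clusters of keratin-expressing cells (Krt5, Krt14, Krt15, Lgals7, Krtdap and Krt1) held 85 cells of E4_C 2-F and at most 2 of any other mouse. No comparison uses these cells.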

How the results depend on the processing

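This part covers alternatives set before the data were examined and 5 settings chosen after they were seen: the looser filter, the looser filter with the run of titles, the run of titles crossed with sex, the median mitochondrial share as a term, and the fit without E3_T 1-M, 2-F and 2-M. Unless a reason is given, the cause was not tested. All changes of direction are listed, with changes of the side of the threshold for gene lists and the DAM-high share and changes of over 1.5-fold for counts of genes.

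Most results kept their side of the threshold and their direction. Over the settings other than leaving out 1 mouse, 5398 of 6523 values of named genes stayed the same, 843 were weaker, 225 stronger and 57 changed direction. Of 425 values of gene lists 331 stayed, 73 were weaker, 6 stronger and 15 changed direction. Of 42 DAM-high values 36 stayed and 6 were weaker. All 368 tests of class shares stayed, but few could pass alone. Counts of genes were less stable: 64 of 129 in microglia-like cells and 36 of 54 in other classes moved by under 1.5-fold.

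With each mouse left out in turn the counts in microglia-like cells ran from 51 (without E3_C 3-M) to 226 (without E3_T 1-F) for E3_T against E3_C, from 282 (without E4_T 1-M) to 745 (without E3_C 3-M) for E4_T against E4_C, and from 0 (without E3_C 1-F) to 18 (without E3_T 3-M) for the interaction. They ran from 210 (without E4_T 1-M) to 490 (without E3_T 3-M) for E4_T against E3_T, from 250 (without E3_C 1-M) to 617 (without E3_C 3-M) for E4_C against E3_C, and, for differences between the sexes in response, from 0 (without E3_C 2-F) to 23 (without E4_T 2-M) for sex by induction and from 6 (without E4_T 1-M) to 89 (without E4_T 2-M) for sex by induction in E4. For males against females they stayed within 1025 to 1377. Of 9480 values of named genes 8882 stayed the same, 480 were weaker, 118 stronger and 0 changed direction.

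Tools and filters moved these counts. DESeq2 gave 197 for E3_T against E3_C, 19 for the interaction, 48 for sex by induction and 63 for sex by induction in E4. Without the filter on low counts edgeR gave 427 for E3_T against E3_C, 977 for E4_T against E4_C, 239 for the interaction, 738 for E4_T against E3_T, 798 for E4_C against E3_C, 156 for sex by induction, 31 for sex by induction in E3 and 265 for sex by induction in E4. Without the sex term it gave 65 for E3_T against E3_C, 298 for E4_T against E4_C and 262 for E4_C against E3_C. The 12 mice of a comparison alone gave 65 for E3_T against E3_C. Titles 1-8 alone gave 216 for E3_T against E3_C. With doublets kept the count was 5 for sex by induction. RLE scaling and a mean of at least 10 CPM moved no count by 1.5-fold or more.

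Subsets and depth moved them as well. Females alone gave 5 for E3_T against E3_C, 30 for E4_T against E4_C, 66 for E4_T against E3_T and 122 for E4_C against E3_C. Males alone gave 10 for E3_T against E3_C, 73 for E4_T against E3_T and 122 for E4_C against E3_C, with fewer mice in both. With 520 cells per mouse, thinned to equal UMIs, the counts fell to 44 for E3_T against E3_C, 94 for E4_T against E4_C, 103 for E4_T against E3_T, 117 for E4_C against E3_C, 380 for males against females and 8 for sex by induction in E4. These settings hold fewer mice or fewer counts by construction. The median mitochondrial share as a term gave 1 for the interaction, 88 for sex by induction and 141 for sex by induction in E4.

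The looser filter, with more cells and counts, gave 265 for E3_T against E3_C, 1375 for E4_T against E4_C, 1 for the interaction, 802 for E4_T against E3_T and 782 for E4_C against E3_C. It also gave 2011 for males against females, 33 for sex by induction and 120 for sex by induction in E4. The adjusted p of the DAM-high share was 0.0703 for E3_T against E3_C and 0.0848 for the interaction, and thinned to 2000 UMIs it was 0.216 for E3_T against E3_C, 0.275 for E4_C against E3_C and 0.39 for the interaction. At 2000 UMIs fewer cells are deep enough to be used.

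The comparison of E4_T with E4_C rests on the run differences of 4 E3 mice once the run of titles is a term. The counts became 1 for E4_T against E4_C, 1 for the interaction, 77 for E4_T against E3_T and 60 for E4_C against E3_C, and 20 for sex by induction and 76 for sex by induction in E4. The single genes left were Cdkn1a and, for the interaction, Mmp2. In other classes they became 0 in neuroblast-like cells with the main filter for E4_T against E4_C, 0 in T cell-like cells for E3_T against E3_C, 0 in astrocyte-like cells for E4_T against E4_C and 1 in astrocyte-like cells for the interaction. The others became 0 in endothelial-like cells for E4_T against E4_C, 0 in endothelial-like cells for the interaction, 0 in neuroblast-like cells for E4_T against E4_C and 1 in neuroblast-like cells for the interaction. The median size of the 628 log2 fold changes fell from 0.52 to 0.25 while their SE rose from 0.13 to 0.29, and 495 kept their sign. For E3_T against E3_C all 127 genes kept their sign and 77 passed, of 130 in all.

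Gene lists (adjusted p) also changed with this term. For E4_T against E4_C, the sets no longer past the threshold were oxidative phosphorylation (0.319), while DAM (9.12e-07), MHC class II (0.00626), MHC class I (4.38e-07), complement (0.0204), lysosome (0.017), glycolysis (0.0137) and ribosomal (0.00674) changed direction. For the interaction, the sets no longer past the threshold were homeostatic (0.179), MHC class II (0.0531), MHC class I (0.179), cholesterol synthesis (0.16) and NF-kB (0.0538), while DAM (0.397) and interferon (0.0252) changed direction. For E4_T against E3_T, the sets no longer past the threshold were MHC class II (0.536), MHC class I (0.745) and glycolysis (0.653), while DAM (0.0001) came past the threshold and interferon (0.000618) changed direction. For E4_C against E3_C, proliferation (0.0268) changed direction.

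Named genes that changed direction with this term were not past the threshold after it. Direction changed for S100a4 (−0.32), Ctss (0.34), C1qb (0.22), C1qa (0.35), Selplg (−0.14), Ndufa4 (−0.3), Spr (0.15), Gapdh (0.01), Uqcrc2 (0.14), Rnh1 (0.02), Ier2 (0.03), Psmb10 (0.35), Npc2 (0.23), Rps2 (0.26) and Psmb8 (0.52) in E4_T against E4_C (log2 values), and, in E4_T against E3_T, for Cxcl9 (1.93) and H2-Q7 (0.37).

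The run of titles crossed with sex gave 260 for E3_T against E3_C, 1 for E4_T against E4_C, 1 for the interaction, 124 for E4_T against E3_T and 106 for E4_C against E3_C. Direction changed for S100a4 (−0.34), Ctss (0.35), C1qb (0.24), C1qa (0.36), Selplg (−0.15), Ndufa4 (−0.3), Spr (0.16), Gapdh (0.01), Uqcrc2 (0.14), Rnh1 (0.03), Ier2 (0.02), Psmb10 (0.36), Npc2 (0.21), Rps2 (0.26) and Psmb8 (0.52) in E4_T against E4_C (log2 values), and, in E4_T against E3_T, for Ifi204 (0.03), Cxcl9 (1.93) and H2-Q7 (0.46).

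The looser filter with the run of titles gave 228 for E3_T against E3_C, 6 for E4_T against E4_C, 2 for the interaction, 89 for E4_C against E3_C, 2275 for males against females, 157 for sex by induction and 324 for sex by induction in E4. Direction changed for Pmvk (0.33), S100a4 (−0.53), Ctss (0.33), Zfp697 (−0.03), C1qb (0.25), C1qa (0.39), Selplg (−0.17), Ndufa4 (−0.33), Gapdh (0.09), Uqcrc2 (0.1), Rnh1 (0.13), Psmb10 (0.33), Timp2 (0.18), Npc2 (0.34), Sod2 (0.01), Rps2 (0.29), Psmb8 (0.55) and Cd14 (0.12) in E4_T against E4_C (log2 values), and, in E4_T against E3_T, for H2-Q7 (0.41).

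Without E3_T 1-M, 2-F and 2-M, a choice based on their own values, the counts became 2 for E3_T against E3_C, 1 for the interaction, 112 for E4_T against E3_T, 21 for sex by induction and 1 for sex by induction in E3. In other classes they became 13 in neuroblast-like cells with the main filter for E4_T against E4_C, 1 in neuroblast-like cells with the main filter for the interaction, 0 in T cell-like cells for E3_T against E3_C, 2 in astrocyte-like cells for E3_T against E3_C, 0 in endothelial-like cells for the interaction and 1 in neuroblast-like cells for E3_T against E3_C. The adjusted p of the DAM-high share was 0.179 for E3_T against E3_C. For E3_T against E3_C, the sets no longer past the threshold were DAM (0.356), MHC class I (0.171) and proliferation (0.0957), while glycolysis (0.377) changed direction. For the interaction, the sets no longer past the threshold were homeostatic (0.27), DAM (0.634), MHC class I (0.0792), cholesterol synthesis (0.0792), oxidative phosphorylation (0.27) and NF-kB (0.0759), while interferon (0.27) changed direction. For E4_T against E3_T, the sets no longer past the threshold were MHC class II (0.625) and MHC class I (0.639), while DAM (1.03e-06) came past the threshold and interferon (0.000241) and glycolysis (0.846) changed direction. For E4_C against E3_C, interferon (0.0186) came past the threshold. The named genes that changed direction, with log2 values, were Cxcl9 (1.81), H2-Q7 (0.56) and Cd74 (0.05) for E4_T against E3_T.

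Camera with an estimated correlation called fewer lists (adjusted p). For E3_T against E3_C, the sets no longer past the threshold were DAM (0.199), MHC class I (0.0677), interferon (0.0642), glycolysis (0.499), oxidative phosphorylation (0.0677), NF-kB (0.0642), proliferation (0.473) and ribosomal (0.101). For E4_T against E4_C, the sets no longer past the threshold were interferon (0.904), oxidative phosphorylation (0.904) and proliferation (0.805). For the interaction, the sets no longer past the threshold were homeostatic (0.152), DAM (0.367), MHC class II (0.0626), MHC class I (0.152), interferon (0.521), cholesterol synthesis (0.134), oxidative phosphorylation (0.576), NF-kB (0.193) and ribosomal (0.231). For E4_T against E3_T, the sets no longer past the threshold were MHC class II (0.342), MHC class I (0.342), interferon (0.689), glycolysis (0.592), NF-kB (0.657), immediate early (0.415) and ribosomal (0.657). For E4_C against E3_C, the sets no longer past the threshold were DAM (0.133), MHC class II (0.332), oxidative phosphorylation (0.522), NF-kB (0.0663), immediate early (0.303) and ribosomal (0.085).

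Fry, a self-contained test, differed from camera as follows (adjusted p). For E3_T against E3_C, the sets no longer past the threshold were DAM (0.0729), glycolysis (0.32) and proliferation (0.32). For E4_T against E4_C, the sets no longer past the threshold were interferon (0.408), oxidative phosphorylation (0.408) and proliferation (0.224), while cholesterol synthesis (0.00937) came past the threshold. For the interaction, the sets no longer past the threshold were homeostatic (0.0578), DAM (0.218), MHC class I (0.0578), interferon (0.353), oxidative phosphorylation (0.321), NF-kB (0.074) and ribosomal (0.0649). For E4_T against E3_T, the sets no longer past the threshold were interferon (0.437), glycolysis (0.149), NF-kB (0.258) and ribosomal (0.316), while cholesterol synthesis (0.0347) came past the threshold. For E4_C against E3_C, the sets no longer past the threshold were MHC class II (0.0838) and oxidative phosphorylation (0.0838), while homeostatic (0.0195) came past the threshold.

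The mice share only a number in the labels, which do not say that it marks a litter, day or batch. The correlation of the deviations of same-numbered mice ran from −0.126 to 0.473 over 2243 genes, with 6 of 12 pairs over 0.1 and 7 of 12 mice correlating best with their own number. With the number as a replicate block the counts in microglia-like cells were 116 for E3_T against E3_C and 615 for E4_T against E4_C. In other classes the replicate block gave 6 in OPC-like cells for E4_T against E4_C, 1 in OPC-like cells for the interaction, 2 in T cell-like cells for the interaction and 47 in astrocyte-like cells for E4_T against E4_C. The oxidative phosphorylation set of E4_T against E4_C had an adjusted p of 0.0567 with it.

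Depth limits what can be seen. In microglia-like cells simulated changes of 1.5-fold were recovered in 44.8% of genes for E3_T against E3_C, and in 3.1% for E4_T against E4_C with the run of titles as a term, so a gene not past the threshold may still have changed by this much. The stricter filter and the tests of CAM-like cells, with limits of 20 or 50 cells per mouse, were not run because too few cells were left.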

Other observations

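The tests named in this part were chosen only after the results were seen.

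Genes around the ROSA26 locus rose together in both induced groups. Of the 15 genes higher in both isoforms 3 lie among the 13 tested genes within 500 kb of Gt(ROSA)26Sor, and 10 of 10,000 random sets of 15 tested genes had 3 within 500 kb of 1 of them (one-sided permutation test, p = 0.0011). Thumpd3 overlaps Gt(ROSA)26Sor, and without it 896 of 10,000 random sets had 2 (the same permutation test, p = 0.0897). Whether a transgene placed in the locus and recombined by tamoxifen raises these genes therefore stays open. Within the same 500 kb Camk1 (log2 −0.43; adjusted p = 0.043) and Arpc4 (−0.40; adjusted p = 0.0229) fell in E4_T.

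Mouse Apoe was nearly absent from microglia-like cells with the looser filter, with 151 counts in 170,536,341 UMIs (0.885 CPM; 0 to 2.06 per mouse). Astrocyte-like cells, the main source of brain apoE, held 96.6 CPM (45.4 to 135) and endothelial-like cells 31.1 CPM (0 to 58.4). Clu, another apolipoprotein of astrocytes, was 1810 CPM in astrocyte-like cells (1170 to 2550) and 6.15 in microglia-like cells.

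An unnamed cluster of 299 cells lies closest to the CAM markers, which were detected in 13.1% of its cells on average. Its top genes include H2-Eb1, Pf4, Ms4a7, Mgl2 and Clec4b1. It held 0.183% of cells in E3_C, 0.192% in E3_T, 0.223% in E4_C and 0.301% in E4_T. With the 20% limit on own markers it was not counted as CAM-like.

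Dpys, a pyrimidine enzyme, had 0 counts in microglia of all E3_C mice and 169 in E4_C (7.0 CPM), at least 35.4-fold. Ifi44, silent in E3_C, reached 3.82 CPM over E3_T, at least 19.3-fold, all of it from E3_T 1-M, 2-F and 2-M.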
